A study of Mus musculus with 84 samples.

How the data were processed

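The series holds 84 mouse samples. RNA was measured in 70 libraries, chromatin accessibility (ATAC-seq) in 12 and TEAD2 binding by 1 ChIP library. An input library is listed among the samples, and no file for it was used here. Per the labels, reprogramming started from MEFs infected with retroviruses for Oct4, Klf4 and Sox2 together with a hairpin, day 0 was the day the viral supernatant was removed, and actinomycin D or DMSO was given for 4 h or 8 h.

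The deposited RNA tables give TPM, a unit of relative transcript abundance, per gene, as the authors made them, for 50692 genes. Per the submitters' processing notes, Bowtie2, SAMtools, MACS2, RSEM and deepTools were used on build mm10, and their versions and settings are not given in the sources used here. The deposited peak lists give the chromosome, start and end position of each peak called by the authors, 1 list per library, with no height or p-value. Peak positions and widths are therefore the only peak values used. A deposited table of spike-in values has 24 per-sample columns whose names could not be matched to samples, so it was not used here and no spike-in scaling was run. TPM holds no read total, so depth per library is unknown and no count-based interval is given for expression. The 10 most abundant genes took 8.43 to 18.3% of TPM in the time course libraries, and mitochondrial transcripts 3.96 to 14.9%. In the time course, libraries numbered 1 listed 14789 to 16443 genes at 1 TPM or more and 3.96 to 6.95% mitochondrial TPM, and libraries numbered 2 listed 13299 to 14885 genes and 7.58 to 14.9%. The correlation of replicates was 0.873 to 0.921 in the time course, 0.96 to 0.973 in the cell lines, 0.942 to 0.957 in the Tead2 experiment and 0.926 to 0.945 in the lifetime experiment.

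Genes are named as the tables name them, and 86 names occur more than once. Gene positions were taken from a RefSeq table of the same assembly, which placed 35088 genes by their identifier. It was used without strand, so distances are from the gene and its ends, not from a transcription start. Samples were grouped by the labels into hairpin, day or cell type, and treatment. The groups, 29 comparisons, 29 gene lists, alternatives and the rule for named genes were fixed before the data were examined.

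Values were log2(TPM + 1), and genes with 1 TPM or more in at least 2 libraries of a fit were kept. Limma 3.58.1 in R 4.3.3 was fitted with 1 mean per group and a trended prior, in 4 separate fits: time course (24 libraries, 12 groups, 21303 genes, 12 residual degrees of freedom), cell lines (18, 9, 17985 and 9), Tead2 (4, 2, 14783 and 2) and lifetime (24, 12, 19290 and 12). Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. A mean of days or hours weights them equally. Persistence is the log2 change from DMSO to actinomycin D in a knockdown minus that in shLuc. Whether replicate numbers pair the samples was checked by the correlation of deviations from the group mean between libraries of the same number: it was 0.276 to 0.497 in the time course and 0.122 to 0.388 in the lifetime experiment, and -0.126 to 0.074 in the cell lines and -0.022 in the Tead2 experiment. Replicate number was therefore read as a pairing in the first pair of experiments and as a number alone in the others, and the planned fit with it as a block is given beside a result where it changes a call or moves a count by more than 1.5 times.

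The 29 lists held 474 genes in 475 entries, of which 473 were found under their own name and 2 through the gene identifier (Ccn1 and Ccn2, named Cyr61 and Ctgf in the tables). They cover m6A writers, erasers and readers, the CCR4-NOT deadenylase, PAN2-PAN3 with decapping and poly(A) binding, mesenchymal genes, collagens and matrix, epithelial genes, the pluripotency network, reprogramming factors, YAP-TEAD targets, Hippo components, the TGF-beta response, cell cycle, p53 targets, interferon-stimulated, inflammatory and immediate early genes, the unfolded protein and amino acid stress response, glycolysis, oxidative phosphorylation, ribosomal proteins, mitochondrial transcripts, and markers of macrophage, endothelial, skeletal muscle, neural, keratinocyte, trophoblast, primitive endoderm and epiblast cells. Each list was tested with limma camera at a preset correlation of 0.01, adjusted over lists within a comparison, and again with the correlation estimated from the residuals. Of all list tests 168 passed, and 22 with the estimated correlation. Members called were counted over all genes and adjusted over the list alone. Reprogramming factors in the time course include the virally expressed ones, which TPM cannot separate from the endogenous genes.

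Named genes are Ythdf1, Ythdf2, Ythdf3 and Tead2, and then those with an adjusted p under 0.05, no overlap between the libraries of the groups (for means, the same sign at each day or hour), at least 5 TPM in the higher arm and a symbol that is not a clone or model name. Of these the 8 with the largest change in each direction were taken, or 5 in the cell lines and for shLuc day 7 against day 1. Up to 4 members of each list described were added by smallest adjusted p. Where a comparison called 5 genes or fewer, Gm16572, Gm25534, Anxa2 and Tpi1 were named after their values were seen. The ES-high and MEF-high sets are the 200 genes with the largest difference between ES and MEF shLuc libraries each way (adjusted p under 0.01). Overlaps of calls were set against the number for independent calls, and the covariance of effects that share shLuc libraries against 20 simulated sets of unchanged groups with the same controls.

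Peak overlaps (GenomicRanges 1.54.1) need 1 shared base, and their intervals are exact binomial 95% intervals, which cover counting error only. A gene was TEAD2-bound with a peak within 5 kb of either end. The pipeline was tested on simulated data with 200 changed genes. In shYthdf2 over 4 days, it recovered 49.3% of genes changed by 1 on the log2 scale and 92.4% of those changed by 2, with 5.56% of calls false. At day 1 alone it recovered 5.97% and 62.1% with 0% false, in ES cells 76.1% and 97% with 4.32% false, for shTead2 32.8% and 86.4% with 8.79% false, and for persistence 8.96% and 54.5% with 2.33% false.

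Alternatives tried were a pseudocount of 0.1, no filter except a TPM above 0 in 1 library, median-ratio scaling, the replicate block, each library left out in turn, one fit of all 46 RNA-seq libraries for shTead2, an overlap of at least 50%, equal numbers of the widest peaks in each list, distances of 1 kb and 50 kb, the wider part of the TEAD2 peaks, and signatures of 50 and 500 genes. The widest peaks replaced a planned choice of the strongest peaks, since the lists give no strength. Means without day 1 or without day 7, simulated groups with the spread left by the block, and the shYthdf2 day 7 peak list shortened to the length of the shYthdf3 list were added after seeing the data. Python 3.11.15 with matplotlib 3.10.9 drew the figures.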

Results

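The series measured how mouse cells on the way from fibroblast to induced pluripotent stem cell, and the cell types at either end of that path, changed when 1 of 2 readers of N6-methyladenosine in RNA was knocked down. The readers were YTHDF2 and YTHDF3, and a short hairpin against luciferase (shLuc) was the control. RNA was sequenced at days 1, 3, 5 and 7 of reprogramming by Oct4, Klf4 and Sox2 in 3 arms (shLuc, shYthdf2 and shYthdf3), which made 24 libraries. A further 18 libraries held embryonic stem (ES) cells, induced pluripotent stem (iPS) cells and mouse embryonic fibroblasts (MEFs) in the same 3 arms, and 4 libraries compared shTead2 with its own shLuc at day 1. Another 24 libraries followed RNA after 4 h or 8 h of actinomycin D, which blocks transcription, or of its solvent DMSO. Every RNA group held 2 libraries. Accessible chromatin was given as 1 peak list per arm and day (12 lists), and binding of the transcription factor TEAD2 as 1 peak list at day 1. Expression was given in TPM, a unit of relative transcript abundance that holds no read total, so the depth of each library is unknown. Log2 changes below are given with their standard error (SE), group values as mean TPM ± SD over n = 2 libraries, and p-values are adjusted values from limma. A mean over days is given without an SD. The p-values measure only the spread between the 2 samples of a group, which may be technical.

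Each hairpin's target was measured first. Ythdf2 (chromosome 4, 132184916 to 132212256, mm10) fell in shYthdf2 by 1.60 ± 0.265 on the log2 scale over the 4 days (adjusted p = 0.0034), from 49.7 to 16.5 TPM. It fell in ES cells, with a log2 change of -1.53 ± 0.184 (adjusted p = 0.00102), from 36.9 ± 1.5 to 12.4 ± 3.8 TPM, and in iPS cells from 51.2 ± 2.47 to 15 ± 0.806 TPM (adjusted p = 0.00075). In MEFs the log2 change of -0.76 ± 0.184 did not pass (adjusted p = 0.071; 16.9 ± 3.29 against 29 ± 1.72 TPM). Ythdf3 (chromosome 3, 16183148 to 16217037) fell in shYthdf3 by 1.19 ± 0.259 over the 4 days (adjusted p = 0.0139), from 33.1 to 14.5 TPM. It fell from 23.6 to 9.88 TPM in ES cells (adjusted p = 0.00736), from 32.2 to 13.9 TPM in iPS cells (adjusted p = 0.00755), and from 42.7 ± 1.14 to 21.6 ± 4.37 TPM in MEFs (adjusted p = 0.0462). Over the 4 days Ythdf3 in shYthdf2 (log2 change 0.26, adjusted p = 0.75), Ythdf2 in shYthdf3 (-0.32, adjusted p = 0.596) and Ythdf1 in either arm (0.27, adjusted p = 0.639, and 0.01, adjusted p = 0.991) did not pass. The 2 day 1 libraries of shYthdf3 differed, with Ythdf3 at 20.4 and 5.21 TPM and Ythdf2 at 71.3 and 22.7 TPM.

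**Figure D1:**
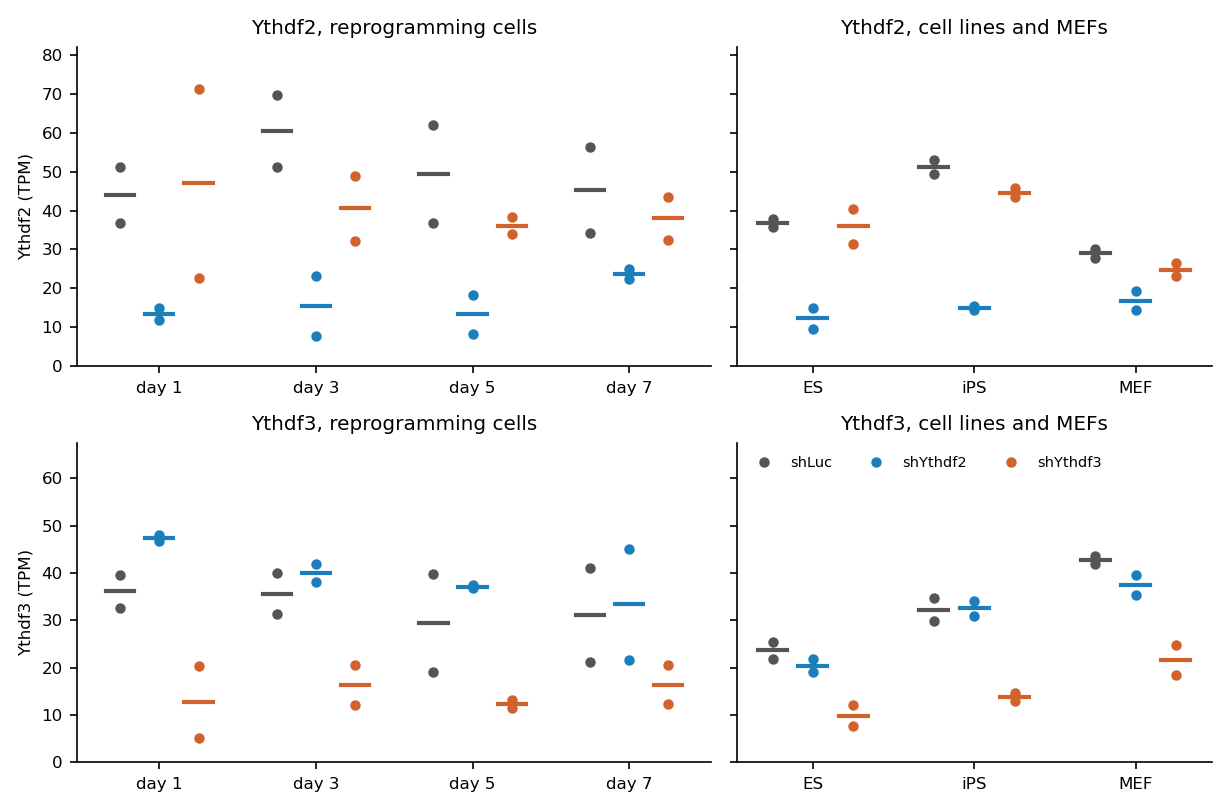
Ythdf2 (top) and Ythdf3 (bottom) in TPM, with 1 point per library and a line at the mean of n = 2 libraries, by day of reprogramming and by cell type in the 3 arms. Ythdf2 averaged 12.4 TPM in shYthdf2 ES cells against 36.9 in shLuc, and Ythdf3 averaged 9.88 TPM in shYthdf3 ES cells against 23.6.

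The change of control cells from day 1 to day 7 was taken as a scale for the knockdown effects. It holds all that changed in the cultures over that time. The named genes that fell were the actin-binding gene Tagln (-5.82 ± 0.512, from 347 to 5.37 TPM, adjusted p = 2.86e-06), smooth muscle actin, Acta2 (-4.71 ± 0.315, from 503 to 18.3 TPM), Fbln5 (-5.25 ± 0.4, from 176 to 3.64 TPM), Il1rn (-5.72 ± 0.735) and Rgs5 (-5.01 ± 0.635). U90926 was listed at 0 in both day 7 libraries and at 32.9 and 26.1 TPM at day 1. Fam25c rose from 1.11 ± 1.57 to 328 ± 2.05 TPM (7.52 ± 0.701, adjusted p = 5.51e-06), H2-Q6, a nonclassical MHC class I gene, by 7.35 ± 0.36, and Igtp, an interferon-inducible GTPase, from 0.79 ± 1.12 to 230 ± 53.9 TPM. Tgtp2 (213 and 146 TPM at day 7) and Sez6 (180 and 103 TPM) were listed at 0 in both day 1 libraries. Over all genes, limma called 836 higher and 618 lower, 1454 together, and 2350 with replicate number as a block. The count was 747 and 760 without day 1 replicate 1 or 2, and 901 and 699 without day 7 replicate 1 or 2.

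Among the gene groups, 13 of 25 epithelial genes rose (18 adjusted over the list alone, median log2 change 2.75), among them Epcam (from 3.48 ± 2.79 to 169 ± 21.6 TPM), Krt8 (4.79), Lsr (3.47) and E-cadherin, Cdh1 (from 2.82 ± 1.16 to 61.2 ± 12.3 TPM). Of 29 pluripotency genes 17 rose (22 adjusted over the list alone, median 2.37), including Alpl, Gdf3 and Tdh by 5.11, 4.15 and 4.22. Of 28 interferon-stimulated genes 22 rose (26 adjusted over the list alone, median 3.18), with Oas2 from 1.35 ± 0.537 to 95.5 ± 30.1 TPM and Isg15 from 4.03 ± 0.445 to 146 ± 44.8 TPM. Of 16 glycolysis genes 6 rose (7 adjusted over the list alone, median 0.75), among them the glucose transporter Slc2a1 (2.75) and the monocarboxylate transporter Slc16a3 (from 6.7 ± 2.47 to 119 ± 14.2 TPM). Collagens and matrix genes went the other way, with 19 of 28 lower (21 adjusted over the list alone, median -1.91), such as Col1a2 (-2.65), Lox (-4.23) and Bgn (-3.40). So did 9 of 25 mesenchymal genes (median -0.75), S100a4 (-2.29) and Twist1 (-1.80) among them, and 5 of 14 genes of the TGF-beta response (8 adjusted over the list alone, median -1.24), such as Inhba (-3.92). These 7 lists passed limma camera with an estimated correlation, at an adjusted p of 0.000285 for epithelial, pluripotency and interferon-stimulated genes, 0.00161 for the TGF-beta response, 0.00449 for collagens and for glycolysis, and 0.0178 for mesenchymal genes, which was 0.0541 with the block. YAP-TEAD targets were lower for 8 of 22 members and higher for 1 (median -0.81), with Axl at -2.17, Myof at -2.22 and Ctgf at -2.38 (adjusted p = 2.24e-07, and adjusted p = 0.0693 with an estimated correlation). Genes higher in ES cells than in MEFs, chosen on the cell line libraries, rose by 1.40 on average (61 of 192 called higher, 3 lower), and genes higher in MEFs fell by 0.82 (53 of 195 called lower, 8 higher). Their adjusted p with an estimated correlation was 0.00193 and 0.0399, and with 500 genes per set the second was 0.135. Tead2 was at 206 ± 53.9 TPM at day 7 against 122 ± 25.7 TPM at day 1 (0.73 ± 0.253, adjusted p = 0.107), which passed with the block (adjusted p = 0.012).

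The labels put YTHDF2 and YTHDF3 among the factors that reprogramming needs, so each knockdown was compared with shLuc over the time course. In shYthdf2, averaged over the 4 days, the genes that rose most were Crct1 (2.53 ± 0.397, from 1.67 to 11.7 TPM, adjusted p = 0.00237), Palm3 (2.42 ± 0.377) and Spon2, which encodes a secreted matrix protein (2.37 ± 0.198, from 5.91 to 28.5 TPM, adjusted p = 1.62e-05). They were followed by Elmod1 (1.96), Pstpip1 (1.92), Ddc, aromatic amino acid decarboxylase (1.88 ± 0.265, from 11.3 to 42.2 TPM), Crybb3 (1.88) and Rnf183 (1.85). Those that fell most were the interferon-inducible guanylate-binding gene Gbp2b (-2.34 ± 0.24, from 130 to 13.9 TPM, adjusted p = 0.000102), Grm4 (-2.00) and protein kinase C beta, Prkcb (-1.88 ± 0.298, from 54.9 to 12.9 TPM). Further falls were those of Dio3 (-1.77), H2-Q6 (-1.71 ± 0.18), osteopontin, Spp1 (-1.69 ± 0.16, from 139 to 43.8 TPM), Neto2 (-1.66) and Ythdf2 itself. Tead2 was at 122 TPM against 167 (-0.45 ± 0.126, adjusted p = 0.0667), which passed with the block (adjusted p = 0.00525).

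Of 22 YAP-TEAD targets 7 rose in shYthdf2 (10 adjusted over the list alone, median 0.44), among them Ajuba (1.03 ± 0.139, from 17.9 to 37.2 TPM), Igfbp3 (0.99 ± 0.137, from 482 to 864 TPM), Ctgf, a connective tissue growth factor (1.28 ± 0.213, from 142 to 307 TPM), and Amotl2 (0.93 ± 0.203). The list passed limma camera at adjusted p = 5.35e-09, but not with an estimated correlation (adjusted p = 0.125). Of 28 cell cycle genes 6 fell (16 adjusted over the list alone, median -0.49) and all 28 had a negative log2 change. Among those that fell were Tpx2 (-0.55 ± 0.12), Ccnb2 (-0.56 ± 0.124), Aurka (-0.65 ± 0.144) and Birc5 (-0.57 ± 0.129), and the list did not hold with an estimated correlation (adjusted p = 1.13e-13, and adjusted p = 0.171 with an estimated correlation). Of 18 p53 targets and cell cycle inhibitors 6 rose and 1 fell (10 and 2 adjusted over the list alone, median 0.51). Sesn2 (0.78 ± 0.102), Phlda3 (0.64), Aen (0.57) and Plk2 (0.87) rose, and Cdkn1b, an inhibitor of cyclin-dependent kinases, fell (-0.70 ± 0.155). That list had adjusted p = 4.22e-06, and adjusted p = 0.0801 with an estimated correlation. Of 28 collagens and matrix genes 3 rose (9 higher and 2 lower adjusted over the list alone, median 0.36). They were Col1a2 (0.86 ± 0.115, from 559 to 922 TPM), Col6a1 (0.80) and Vcan (0.78), and the list had adjusted p = 5.75e-05, and adjusted p = 0.391 with an estimated correlation. The TGF-beta response had a median of 0.30 over 14 genes (adjusted p = 0.00465, and adjusted p = 0.127 with an estimated correlation).

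Further changes lay in lists that did not pass as a whole. The mesenchymal regulators Twist1 (-0.50 ± 0.117) and Twist2 (-0.66 ± 0.171) fell, as did the epithelial genes Lsr (-1.20 ± 0.223) and Spint2 (-0.85 ± 0.194), and the m6A-related genes Igf2bp2 (-0.87 ± 0.136) and Zc3h13 (-0.84 ± 0.203). Over the 4 days limma called 755 genes in shYthdf2, 444 higher and 311 lower, and 1609 with replicate number as a block. Of the 755, 233 differed more than 2-fold. The count was 380 without shYthdf2 day 5 replicate 2, 436 without shLuc day 1 replicate 2, 448 without shYthdf2 day 3 replicate 2, 450 and 468 without shYthdf2 day 1 replicate 2 or 1, 479 without shLuc day 5 replicate 1, and 492 without shLuc day 7 replicate 2. It was 395 with day 7 left out.

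In shYthdf3, averaged over the 4 days, the largest rises were those of the aldo-keto reductase Akr1c21 (3.05 ± 0.249, from 0.185 to 13 TPM, adjusted p = 1.46e-05), Grm2 (2.65 ± 0.365) and Krtap13 (2.51). Further rises were those of the retinol dehydrogenase Rdh16 (2.38), Ms4a4b (2.38), Crct1 (2.33 ± 0.397), Kng2 (2.21 ± 0.272, from 3.77 to 29.6 TPM) and Hgd (2.14). The largest falls were those of Slc16a3, which exports lactate (-2.44 ± 0.3, from 36.3 to 2.97 TPM, adjusted p = 0.000279), Apoa2 (-2.34) and Prkcb (-2.23 ± 0.298, from 54.9 to 11.4 TPM). After them came Ccdc106 (-1.88), Nkain4 (-1.88), Plac8 (-1.85), the prolyl hydroxylase gene Egln3 (-1.84 ± 0.217, from 22 to 3.46 TPM) and Chrm4 (-1.79). Tead2 did not pass (0.14, adjusted p = 0.657). Glycolysis genes were lower. Of 16 members 5 fell (8 lower and 1 higher adjusted over the list alone, median -0.41), namely Slc16a3, lactate dehydrogenase Ldha (-0.51 ± 0.092, from 512 to 328 TPM), Slc2a1 (-0.54 ± 0.122), Pfkl (-0.75 ± 0.179) and Tpi1 (-0.55 ± 0.133). The list had adjusted p = 8.05e-06, and adjusted p = 0.0596 with an estimated correlation. At day 7 alone the median was -0.84, and Ldha fell from 919 ± 88 to 366 ± 60.2 TPM, Slc16a3 from 119 ± 14.2 to 8.03 ± 5.43 TPM and Slc2a1 from 210 ± 15.7 to 79.8 ± 11.3 TPM (5 of 16 members called, 11 adjusted over the list alone). That call held with an estimated correlation (adjusted p = 0.0012). In shYthdf2 the day 7 median was -0.49, with 0 of 16 members called and 4 lower adjusted over the list alone, such as Ldha at 538 ± 94.8 TPM (adjusted p = 7.76e-06 for the list, and adjusted p = 0.059 with an estimated correlation). The arms were not tested against each other at day 7 alone.

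In shYthdf3 the immediate early genes Junb (0.87 ± 0.14, from 252 to 451 TPM), Ier2 (0.87 ± 0.188) and Egr2 (1.62 ± 0.373) rose, 3 of 16 in that list (median 0.33, adjusted p = 0.00186, and adjusted p = 0.502 with an estimated correlation). The interferon-related genes Irf7 (0.88 ± 0.142) and Oas2 (0.89 ± 0.161) rose, 2 of 28 (8 higher and 2 lower adjusted over the list alone, median 0.38, adjusted p = 0.00541, and adjusted p = 0.502 with an estimated correlation). Cell cycle genes Mcm7 (-0.52), Mcm3 (-0.68), Mki67 (-0.81 ± 0.199) and Birc5 (-0.49) fell, 4 of 28 (6 adjusted over the list alone, median -0.39, adjusted p = 1.29e-08, and adjusted p = 0.451 with an estimated correlation). Psat1 (-1.05 ± 0.097, from 123 to 60.3 TPM) and Phgdh (-1.00 ± 0.157), enzymes of serine synthesis in the list of unfolded protein and amino acid stress genes, fell (adjusted p = 0.0203 for the list, and adjusted p = 0.151 with an estimated correlation). Of 25 mesenchymal genes Prrx1 (-0.90 ± 0.217), Foxc1 (-0.65) and Thy1 (-1.41 ± 0.38) fell (adjusted p = 0.0203, and adjusted p = 0.502 with an estimated correlation). Ribosomal protein genes had a median of -0.22 (adjusted p = 0.00563, and adjusted p = 0.345 with an estimated correlation). Col1a2 fell (-0.68 ± 0.115, from 559 to 335 TPM) with Fbln2 (-0.70) and Thbs2 (-0.66), while the matrix list had a median of 0.12, a mean of 0.02 and a test that pointed down without passing (adjusted p = 0.877). Fto, an m6A demethylase, fell by 0.51 ± 0.113. In all, limma called 1121 genes, 589 higher and 532 lower, of which 458 differed more than 2-fold, and 2228 genes with the block.

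**Figure D2:**
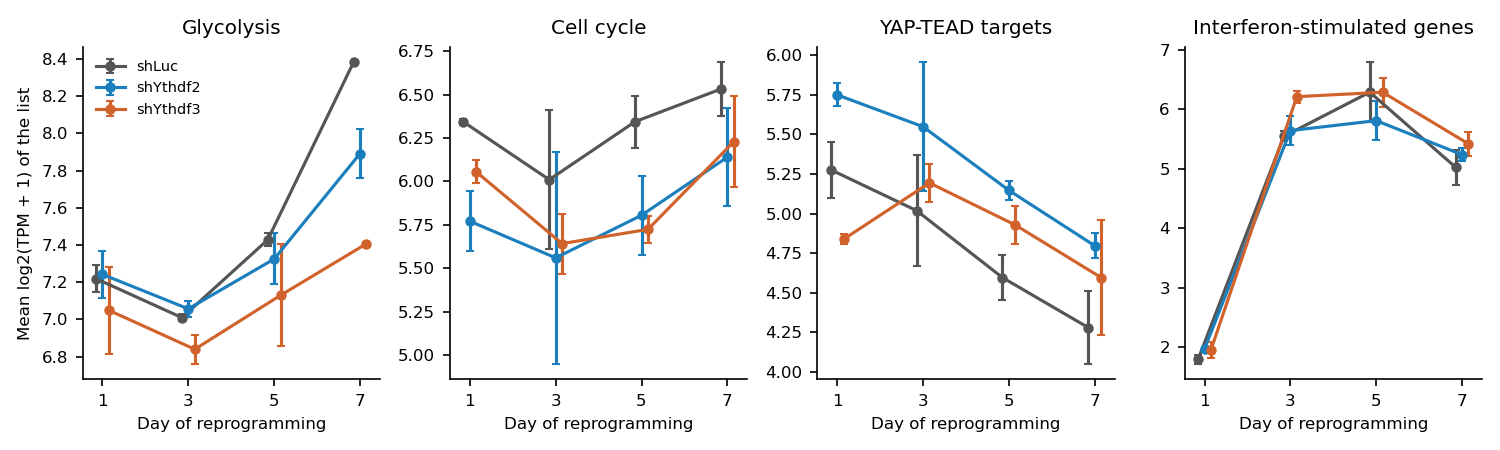
Mean log2(TPM + 1) of the members of 4 gene lists by day of reprogramming, with points at the mean of n = 2 libraries and bars of 1 SD, in the 3 arms. Glycolysis genes in shYthdf3 were lower than in shLuc at day 7, with a median log2 change of -0.84 (adjusted p = 0.0012 with an estimated correlation), and YAP-TEAD targets in shYthdf2 had a median of 0.44 over the 4 days (adjusted p = 0.125 with an estimated correlation).

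Taken day by day, shYthdf2 gave 3, 17, 38 and 28 called genes at days 1, 3, 5 and 7 (26, 137, 182 and 73 with the block), and shYthdf3 gave 23, 43, 136 and 122 (141, 195, 422 and 343 with the block). With a pseudocount of 0.1 the shYthdf2 counts at days 1, 3 and 5 were 12, 7 and 23 and those of shYthdf3 35, 17 and 75. Without the filter shYthdf2 gave 17 and 34 at days 1 and 3, and with median-ratio scaling 11 at day 1. The share of higher calls in shYthdf2 at day 1 was 33.3%, and 45.5% with median-ratio scaling, and in shYthdf3 at day 3 it was 41.9% and 52.8%. The day counts rested on single libraries. At day 1 the shYthdf2 count was 6 without shLuc replicate 1, and the shYthdf3 count was 8 and 3 without shLuc replicate 1 or 2, 14 without shYthdf3 replicate 1 and 473 without shYthdf3 replicate 2, where the share of higher calls went from 39.1% to 89.6%. At day 3 the shYthdf2 count was 0 without shLuc replicate 2, 71 without shYthdf2 replicate 1 and 2 without its replicate 2, and the shYthdf3 count was 1 without shLuc replicate 2 and 0 without shYthdf3 replicate 2. At day 5 the shYthdf2 count was 3 and 1 without shLuc replicate 1 or 2, and 21 and 0 without shYthdf2 replicate 1 or 2. The shYthdf3 count there was 32 and 4 without shLuc replicate 1 or 2, and 34 and 42 without shYthdf3 replicate 1 or 2. At day 7 the shYthdf2 count was 15 and 2 without shLuc replicate 1 or 2, and 14 and 1 without shYthdf2 replicate 1 or 2, and the shYthdf3 count was 33, 12, 53 and 25 in the same order of arms. Whether an effect changed from day 1 to day 7 was tested as a difference of differences. For shYthdf2, Gm16572 alone passed (3.10 ± 0.383, adjusted p = 0.0122, 604 genes at an unadjusted p under 0.05). A pseudocount of 0.1 gave 0 genes and no filter 18. Leaving out 1 library gave 5 genes without shYthdf2 day 1 replicate 2 and 0 without any other library of the 4 groups. For shYthdf3, limma called 0 genes (1442 at an unadjusted p under 0.05), 34 with the block, 26 without the filter, 3 with median-ratio scaling, 306 without shYthdf3 day 1 replicate 2, 2 without shYthdf3 day 7 replicate 2 and 1 without shLuc day 1 replicate 1. Median-ratio scaling moved the all-gene median of that difference from 0.13 to 0.

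Set against each other over the 4 days, the knockdowns differed in 1493 genes, 759 higher and 734 lower in shYthdf2 (2746 with the block). Of 22 YAP-TEAD targets 9 were higher in shYthdf2 and 1 lower (median 0.55, adjusted p = 1.59e-05, and adjusted p = 0.228 with an estimated correlation), including Axl (0.80 ± 0.116), the tissue factor gene F3 (1.66 ± 0.322, 45.9 against 11.8 TPM), Ccdc80 (1.34) and Tgfb2 (0.94). Inhba, an activin subunit, was at 20.1 TPM in shYthdf2 against 2.09 TPM in shYthdf3 (2.28 ± 0.29), and the TGF-beta response list (median 0.44) and the p53 list (median 0.30) held with an estimated correlation, both at adjusted p = 0.0446. Of the p53 list 4 of 18 were higher: Phlda3 (0.76), Gdf15 (1.27), Cdkn1a, which encodes p21 (0.84 ± 0.198, 742 against 408 TPM), and Trp53inp1 (1.13). Immediate early genes Junb (-0.67), Ier2 (-0.82), Egr2 (-1.48) and Egr3 (-1.48) were lower in shYthdf2. Of the deadenylation genes, Pan2 was lower in shYthdf2 (-0.95 ± 0.155, 10.5 against 21.3 TPM, adjusted p = 0.00165), as was the decapping gene Dcp1b (-0.93 ± 0.215). Glycolysis genes were higher in shYthdf2 than in shYthdf3 for 3 of 16 members (6 adjusted over the list alone, median 0.28, adjusted p = 0.000364, and adjusted p = 0.078 with an estimated correlation). Genes called in both knockdowns against shLuc numbered 127 higher in both, 76 lower in both and 12 in opposite directions. Independent calls would give 12.3 and 7.77, but calls against the same shLuc libraries are not independent. Across 21303 genes, which are not independent replicates, the 2 effects had r = 0.396 and a covariance of 0.0783. Unchanged groups simulated with the same controls had r = 0.505, which the sharing of controls alone gives, and a covariance of 0.0706 (0.063 to 0.0807 over 20 simulations) with the full spread within groups. That spread includes the difference between replicate numbers, which cancels between the arms, and with it taken out as a block the simulated covariance was 0.042 (0.0396 to 0.0445). With no library shared, each knockdown replicate set against the shLuc replicate of its number gave covariances of 0.0377 and 0.0375 (r = 0.136 and 0.127). Both replicates of each knockdown set against 1 replicate of shLuc, a different one for each, gave -0.076 and -0.0693 (r = -0.215 and -0.201), but that puts the difference between replicate numbers into the 2 effects with opposite signs.

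The cell line comparisons asked what the knockdowns did in pluripotent cells and in fibroblasts. In ES cells glycolysis genes rose in both knockdowns. In shYthdf2 12 of 16 glycolysis genes rose (14 adjusted over the list alone, median 0.66), with Tpi1 from 254 to 679 TPM (1.41 ± 0.065, adjusted p = 5.73e-07), Pgk1 from 399 ± 28.4 to 841 ± 37.3 TPM (1.08), Hk1 (1.31 ± 0.095) and Ldha from 945 ± 44.3 to 1616 ± 43 TPM (0.77). In shYthdf3 12 of 16 rose as well (15 adjusted over the list alone, median 0.68), with Tpi1 at 1.30, Pgk1 at 0.98, Aldoa at 0.80 and Ldha at 0.70. The list passed with an estimated correlation in both (adjusted p = 0.00801 and 0.00475). Among the largest changes of single genes in shYthdf2 were rises of Ndufa4l2 (3.07 ± 0.289, from 2.78 ± 0.0141 to 30.8 ± 0.0495 TPM), Bnip3, a mitophagy receptor gene (2.29 ± 0.159, from 23.5 ± 5.08 to 118 ± 7.64 TPM), Slc16a3 (2.20 ± 0.187) and the histone gene Hist1h2ad (3.36 ± 0.759). Among the falls were those of Gbx2 (-1.84 ± 0.27), Halr1 (-1.90 ± 0.272) and Ptp4a1 (-1.79 ± 0.41). Snora41 was listed at 0 in both shLuc libraries and at 85.8 and 76.6 TPM in shYthdf2. Snora70 (56 and 116 TPM in shLuc) and Snord15a (48.8 and 28.1 TPM) were listed at 0 in every knockdown library of ES cells. In shYthdf3, Ndufa4l2 (3.29 ± 0.289), Slco1a6 (2.22 ± 0.48), Bnip3 (2.19 ± 0.159), Pgm2 (2.11 ± 0.099) and Col26a1 (2.04 ± 0.365) rose, and Pitx3 (-2.17 ± 0.453), T (-2.02 ± 0.402) and Spry4, a feedback inhibitor of FGF signalling (-1.43 ± 0.161), fell.

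Of 30 pluripotency genes in shYthdf2 ES cells 1 rose and 5 fell (2 and 10 adjusted over the list alone, median -0.18). Lin28a (-1.36 ± 0.127, from 73.8 to 28.3 TPM), Klf5 (-1.00 ± 0.116), Nr0b1 (-0.63), Sall4 (-0.53) and Tdh (-0.44) fell and Fgf4 rose (0.74 ± 0.081). The list had adjusted p = 0.00359, and adjusted p = 0.218 with an estimated correlation. Of 7 epiblast and early germ layer genes 3 rose, namely Lefty2 (1.50 ± 0.073, from 176 to 498 TPM), Lefty1 (1.48 ± 0.119) and Otx2 (1.24 ± 0.208), and T, which encodes brachyury, fell (-1.67 ± 0.402). That list had adjusted p = 0.00495, and adjusted p = 0.194 with an estimated correlation. Myc fell in both knockdowns (-1.30 ± 0.115 in shYthdf2, from 32.8 to 12.8 TPM, and -1.00 ± 0.115 in shYthdf3). In shYthdf3 Lefty1 (1.67 ± 0.119) and Otx2 (1.36 ± 0.208) rose and Lin28a fell (-0.59 ± 0.127). YAP-TEAD targets had a median of -0.10 there (adjusted p = 0.048, and adjusted p = 0.702 with an estimated correlation). Over all genes, limma called 656 genes in shYthdf2 ES cells (343 higher, 313 lower) and 295 in shYthdf3 (169 and 126). The first count was 366 and 323 without shLuc replicate 1 or 2, and 217 and 207 without shYthdf2 replicate 1 or 2. The second was 131 and 164 without shLuc replicate 1 or 2, and 192 without shYthdf3 replicate 2. Called higher in both were 100 genes and lower in both 51 (3.22 and 2.19 if independent). Across genes the effects had a covariance of 0.139 (r = 0.58), against 0.0802 (r = 0.497) in simulated unchanged groups with shared controls.

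In iPS cells glycolysis genes rose again, 9 of 16 in shYthdf2 (12 adjusted over the list alone, median 0.48, adjusted p = 0.041 with an estimated correlation) and 12 of 16 in shYthdf3 (13 adjusted over the list alone, median 0.53, adjusted p = 0.00888 with an estimated correlation). Hk1 rose by 1.16 ± 0.095, Tpi1 from 269 ± 3.63 to 440 ± 26.7 TPM and Slc16a3 from 24.6 ± 1.45 to 77.2 ± 4.17 TPM in shYthdf2. Pgk1 rose from 453 ± 1.52 to 794 ± 26 TPM, Tpi1 by 0.80 and Pfkl by 0.89 in shYthdf3. The genes that rose most in shYthdf2 were Copz2 (3.17 ± 0.213), Smim22 (2.18), Ndufa4l2 (2.11 ± 0.289), A2m (1.93) and Mettl22 (1.72). In shYthdf3 they were Duxbl2 (2.62), Ndufa4l2 (2.52 ± 0.289), Copz2 (2.32), Lefty1 (2.30 ± 0.119, from 47.3 to 236 TPM) and Zscan5b (2.18). Snord15a (19.9 and 20.7 TPM in shLuc) and Mir6340 (154 and 57.6 TPM) were listed at 0 in every knockdown library. Snora70 (11.4 and 27.1 TPM in shLuc) was listed at 0 in both shYthdf2 libraries and at 0.85 and 0 TPM in shYthdf3. Snora73b, at 29.9 and 51.4 TPM in shLuc, was at 0.01 and 0 TPM in shYthdf2. Etv4 (-1.70 ± 0.19) and Spry4 (-1.68 ± 0.161) fell in shYthdf3.

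Of 7 epiblast genes in iPS cells, Lefty2 (1.37 ± 0.073), Lefty1 (1.61 ± 0.119) and Otx2 (0.95) rose in shYthdf2 (adjusted p = 0.000686, and adjusted p = 0.0786 with an estimated correlation), and 2 rose in shYthdf3 (adjusted p = 0.0114, and adjusted p = 0.23 with an estimated correlation). Lin28a (-0.93 ± 0.127) fell and Fgf4 (0.70) rose in shYthdf2. In shYthdf3 Dppa3 rose from 18.8 ± 2.8 to 45 ± 3.88 TPM, and Tfcp2l1 (-0.68 ± 0.104) and Tbx3 (-0.63) fell. Myc fell in both (-0.99 and -1.36). In all, limma called 446 genes in shYthdf2 (284 higher, 162 lower) and 520 in shYthdf3 (215 and 305). The shYthdf3 count was 310 with a pseudocount of 0.1. With median-ratio scaling the share of higher calls in shYthdf3 moved from 41.3% to 53.4%. Without shLuc replicate 1 or 2 the counts were 131 and 104 for shYthdf2 and 145 and 153 for shYthdf3. Without shYthdf2 replicate 1 or 2 the count was 117 and 174, and without shYthdf3 replicate 1 or 2 it was 155 and 123. Between ES and iPS cells, which share no library, 135 genes were higher in both and 77 lower in both in shYthdf2 (5.42 and 2.82 if independent), and 90 and 67 in shYthdf3 (2.02 and 2.14). Within iPS cells the knockdowns shared 92 higher and 63 lower genes (3.4 and 2.75 if independent), with a covariance of 0.119 across genes (r = 0.508), against 0.0804 (r = 0.499) simulated.

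**Figure D3:**
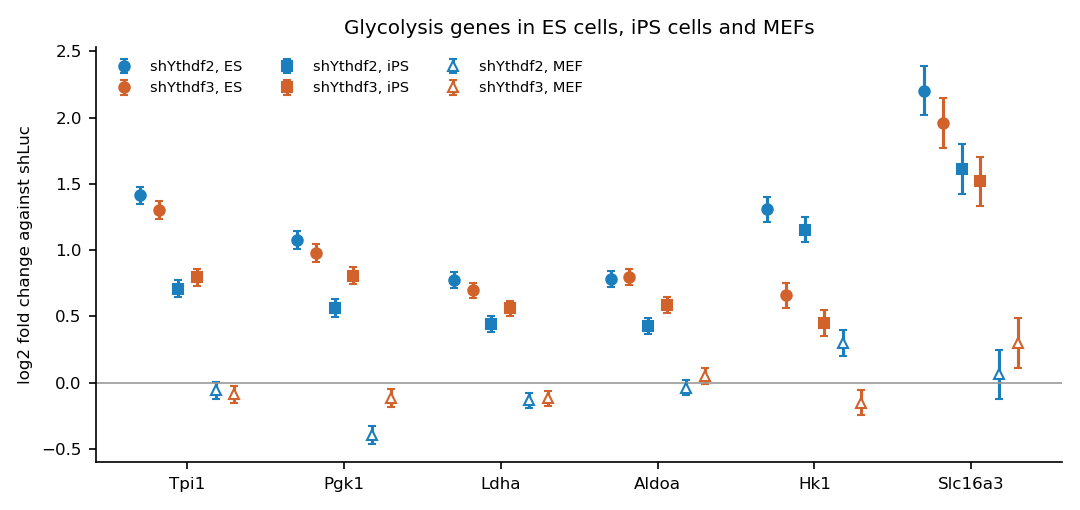
Log2 fold change against shLuc of 6 glycolysis genes in ES cells, iPS cells and MEFs, with bars of 1 SE from limma (n = 2 libraries per group). Tpi1 was at 1.41 and 1.30 in the ES cell knockdowns.

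In MEFs shYthdf2 lowered cell cycle genes: 9 of 28 fell (24 adjusted over the list alone, median -0.41), with the replication genes Mcm5 at -0.48 ± 0.053, Pcna at -0.49 ± 0.058 (from 110 ± 0.474 to 78.1 ± 0.417 TPM) and Mcm3 at -0.62 ± 0.092, and the call held with an estimated correlation (adjusted p = 0.00146). The chromatin gene Hmga2 (-1.34 ± 0.14, from 80.3 to 31.2 TPM), the proliferin gene Prl2c2 (-1.66 ± 0.144), Ahcy (-1.94), Srl (-1.43) and the checkpoint kinase gene Chek1 (-1.14 ± 0.176) fell most. Clec3b (2.07 ± 0.3), angiotensinogen, Agt (2.02 ± 0.294), the acute-phase gene Saa3 (1.82 ± 0.289, from 40 to 143 TPM), Ifitm1 (1.81) and clusterin, Clu (1.54 ± 0.26), rose most. Matrix genes Postn (1.39 ± 0.225), Lum (0.99), Dcn (0.75) and Sparc (0.43) rose, 4 of 28 (median 0.31, adjusted p = 5.35e-06, and adjusted p = 0.212 with an estimated correlation). Il6 (1.05 ± 0.162) and Saa3 rose among 15 inflammatory genes (adjusted p = 0.00147, and adjusted p = 0.212 with an estimated correlation). Pabpc1 (-0.37) and Pabpc4 (-0.38), which bind poly(A) tails, fell (adjusted p = 0.0314 for the PAN2-PAN3 list, and adjusted p = 0.582 with an estimated correlation), as did Mettl3, the m6A methyltransferase (-0.64, adjusted p = 0.0153 for the m6A list, and adjusted p = 0.582 with an estimated correlation). Ccng1 (-0.40) and Cdkn1a (-0.34) fell among p53 targets (adjusted p = 0.0228, and adjusted p = 0.469 with an estimated correlation), and 2 of 16 glycolysis genes fell (median -0.09, adjusted p = 0.00853, and adjusted p = 0.469 with an estimated correlation).

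In shYthdf3 MEFs the p53 targets Ccng1 (-0.82 ± 0.081, adjusted p = 0.000897), Cdkn1a (-0.65 ± 0.074, from 132 ± 4.29 to 83.6 ± 2.32 TPM) and Eda2r (-0.83 ± 0.122) fell, 3 of 18 (10 adjusted over the list alone, median -0.27, adjusted p = 8.36e-07, and adjusted p = 0.0948 with an estimated correlation). Klf4 (-1.18 ± 0.179), Sox5 (-1.17), Depdc7 (-1.16), Blm (-1.11) and Lin54 (-0.98) fell, and Gstm2 (0.96 ± 0.15), Pcca (0.62), Nfu1 (0.58), Selenoh (0.52) and Pcolce (0.49) rose. Cell cycle genes had a median of -0.21 (1 higher and 12 lower adjusted over the list alone, adjusted p = 8.36e-07, and adjusted p = 0.0948 with an estimated correlation), and m6A genes -0.20 (adjusted p = 0.0014, and adjusted p = 0.626 with an estimated correlation). In all, limma called 262 genes in shYthdf2 MEFs (87 higher, 175 lower) and 113 in shYthdf3 (18 and 95). With median-ratio scaling the higher share moved from 33.2% to 43.7% in shYthdf2 and from 15.9% to 29.4% in shYthdf3. The first count was 82 and 34 without shLuc replicate 1 or 2 and 88 without shYthdf2 replicate 2. The second was 44 and 17 without shLuc replicate 1 or 2 and 548 without shYthdf3 replicate 1. It was also 51 with median-ratio scaling, 190 with a pseudocount of 0.1 and 72 with the block. Both knockdowns shared 7 higher and 35 lower genes (0.0871 and 0.924 if independent), with a covariance of 0.0899 across genes (r = 0.469), against 0.0799 (r = 0.499) simulated.

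The difference of the effects between cell types was tested itself. For glycolysis genes the effect in MEFs minus that in ES cells had a median log2 of -0.70 in shYthdf2 and -0.79 in shYthdf3 (adjusted p = 0.00555 and 0.00954 with an estimated correlation). Over all genes, 210 passed for shYthdf2 (88 with a more positive effect in MEFs, 122 more negative) and 132 for shYthdf3 (37 and 95, with the positive share moving from 28% to 45.3% with median-ratio scaling). The shYthdf3 count was 86 with that scaling and 44 with the block. Bnip3 (-2.40 ± 0.225 and -2.44 ± 0.225) and Ndufa4l2 (-3.09 ± 0.409 and -3.22 ± 0.409) passed in both. Leaving out any 1 library gave 54 to 115 genes for shYthdf2, the lowest without ES shYthdf2 replicate 1, and 32 to 574 for shYthdf3, the lowest without MEF shLuc replicate 2 and the highest without MEF shYthdf3 replicate 1. Between iPS and ES cells 3 genes differed for shYthdf2, Tpi1 (-0.71 ± 0.092), Anxa2 (-1.38 ± 0.146) and Gm25534, and Gm25534 alone for shYthdf3 (1200 and 1122 genes at an unadjusted p under 0.05).

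Tead2 was knocked down at day 1. Tead2 (chromosome 7, 45215792 to 45233468) was at 38 and 29.3 TPM in shTead2 against 92.9 and 92.1 TPM in shLuc, with a log2 change of -1.44 ± 0.17 that did not pass over all genes (adjusted p = 0.213). In limma 13 genes were called, 12 higher and 1 lower, and 983 had an unadjusted p under 0.05. The named ones were listed at 0 in both shLuc libraries: Rny3 (134 and 284 TPM in shTead2), Mir703 (72 and 168), Snord22 (65.9 and 47.5), Snora65 (27.3 and 31.3), Snora70 (30.3 and 22.8) and S100a8, a calcium-binding protein gene of myeloid cells (18.1 and 15.3). YAP-TEAD targets had a median of -0.21 over 22 genes and did not pass as a list (adjusted p = 0.344), nor did Hippo pathway components (-0.10, adjusted p = 0.177). Endothelial markers had a median of 3.04 over 9 genes, 8 of them higher adjusted over the list alone. Cdh5 was at 75.4 ± 48 TPM against 0.3 ± 0.0283, Pecam1 at 13.8 ± 3.32 against 0.305 ± 0.219 and Egfl7 at 58.5 ± 28.6 against 5.03 ± 3.69 (adjusted p = 6.44e-13, and adjusted p = 0.434 with an estimated correlation). Epithelial genes (median 0.69, adjusted p = 0.00037, and adjusted p = 0.6 with an estimated correlation), trophoblast genes (1.11, adjusted p = 0.00165, and adjusted p = 0.6 with an estimated correlation, with Eomes at 23.6 ± 24.2 against 0.59 ± 0.382 TPM), primitive endoderm genes (0.96, adjusted p = 0.00185, and adjusted p = 0.6 with an estimated correlation) and mitochondrial transcripts (0.29, adjusted p = 0.00037, and adjusted p = 0.6 with an estimated correlation) had positive medians. Collagens had a median of -0.32 (adjusted p = 0.000563, and adjusted p = 0.627 with an estimated correlation). The gene count was 3 without shTead2 replicate 1, 300 without its replicate 2, and 8 without either shLuc library, and one fit of all 46 RNA libraries gave 168. Without the filter limma called 0 genes, so the named ones lost their calls there.

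Actinomycin D asked which transcripts lasted. After 8 h in shLuc, limma called 294 genes higher and 5494 lower relative to DMSO, with an all-gene median of -0.63, and after 4 h 79 higher and 2402 lower, with a median of -0.31 (4339 genes with the block). Median-ratio scaling moved those medians to -0.19 and -0.08 and the share of higher calls from 5.08% to 33.5% and from 3.18% to 13.7%. TPM are relative values, so a gene called higher was one that lasted longer than the average transcript. The 4 h count was 1315 without actinomycin D replicate 1 and 1464 without DMSO replicate 2. At 8 h short-lived transcripts fell below the rest, as 13 of 16 immediate early genes did (median -3.73), such as Ier3 (-5.09), Jun (-4.65), Fosl1 (-3.85) and Ier5 (-3.40), with adjusted p = 2.46e-05 and adjusted p = 0.408 with an estimated correlation. Of 13 CCR4-NOT genes 10 fell (median -2.41), with Tob1 at -4.68 and Cnot11 at -2.94 (adjusted p = 0.000131, and adjusted p = 0.208 with an estimated correlation). Of 19 m6A genes 14 fell (median -2.34), including Ythdf1 (-3.56), Alkbh5 (-2.98), Wtap (-2.81) and Ythdf2 (-2.64), with adjusted p = 0.000347 and adjusted p = 0.444 with an estimated correlation. Of 18 p53 targets 13 fell, such as Sesn2 (-4.82) and Cdkn1a (-2.77, from 674 to 97.5 TPM; adjusted p = 0.000347, and adjusted p = 0.208 with an estimated correlation). Matrix genes lasted, with 9 of 28 higher and 1 lower (median 0.69), among them Fbln5 (1.40), Bgn (1.23) and Sparc (1.00), with adjusted p = 8.47e-16 and adjusted p = 0.0503 with an estimated correlation. Ribosomal protein genes had a median of 0.51 (adjusted p = 8.21e-07, and adjusted p = 0.408 with an estimated correlation).

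The lifetime experiment asked whether a knockdown let transcripts last longer, which was tested as the difference between knockdown and shLuc in the change from DMSO to actinomycin D, averaged over 4 h and 8 h. In shYthdf2 the difference was 1.25 ± 0.175 for Ywhag, a 14-3-3 protein gene (adjusted p = 0.0189), -2.03 ± 0.254 for Etfdh (adjusted p = 0.0145) and -1.16 ± 0.154 for Snx3 (adjusted p = 0.0147), and in shYthdf3 it was -1.89 ± 0.199 for Pcbp1, a poly(C)-binding protein gene (adjusted p = 0.00157). Of 100 splits of the libraries, the real one included, 33 gave as many genes in shYthdf2 and 41 in shYthdf3, so chance cannot be excluded for either count. With 1 library left out Ywhag lost its call for 7 of 16 libraries (adjusted p up to 0.0959), Snx3 for 4 (up to 0.0676), Etfdh for 1 (0.0574) and Pcbp1 for 0. All 3 calls of shYthdf2 were lost without shLuc actinomycin D 4 h replicate 2, and those of Ywhag and Snx3 without shLuc DMSO 4 h replicate 1 or shYthdf2 actinomycin D 8 h replicate 2. Snx3 was also lost without shLuc DMSO 8 h replicate 2, and Ywhag without shYthdf2 actinomycin D 4 h or 8 h replicate 1 or shYthdf2 DMSO 4 h or 8 h replicate 2. Median-ratio scaling ended the calls of Ywhag (adjusted p = 0.217) and Snx3 (adjusted p = 0.114). Ythdf2 did not pass in shYthdf2 (1.57 ± 0.358, adjusted p = 0.523). These 4 were the only genes called (10 in each knockdown with the block, 5 and 19 without the filter, 5 and 2 with a pseudocount of 0.1, 621 and 653 at an unadjusted p under 0.05). The self-test found 8.96% of transcripts whose simulated log2 change was 1 and 54.5% of those at 2 in this comparison. For shYthdf2 the count was 9 and 6 without shLuc 8 h actinomycin D or DMSO replicate 1 and 5 without shLuc DMSO 4 h replicate 2, and with median-ratio scaling 0% of the calls were higher in place of 33.3%. For shYthdf3 it was at most 5, without shLuc DMSO 8 h replicate 1, and no fewer than 1. In DMSO alone Ythdf2 fell in shYthdf2 from 47.8 to 13.6 TPM (-1.74 ± 0.253, adjusted p = 0.00447), and Ythdf3 was at 7.67 against 40.9 TPM in shYthdf3 (-2.33 ± 0.562, adjusted p = 0.0777, and 3.69e-06 with the block). There 66 genes differed in shYthdf2 (29 higher, 37 lower; 330 with the block) and 135 in shYthdf3 (35 and 100; 737 with the block and 73 with median-ratio scaling). Cell cycle genes in shYthdf2 had a median of -0.30 in DMSO, a call that held with an estimated correlation (adjusted p = 0.0171) and was lost there with the block (0.124). Tgfbi fell in shYthdf3 (-1.00 ± 0.148), in a TGF-beta list with median -0.55 (adjusted p = 0.0153, and adjusted p = 0.585 with an estimated correlation). The DMSO count for shYthdf2 was 36 without shLuc 8 h replicate 2 and 39 without shLuc 4 h replicate 2 or shYthdf2 8 h replicate 2. For shYthdf3 it was 66 without shLuc replicate 2 at 4 h or at 8 h, and from 72 to 88 without shLuc 8 h replicate 1 or any 1 of the shYthdf3 libraries.

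Accessible chromatin was compared by the overlap of peak lists, with 1 library per arm and day and so no replicates. In shLuc there were 60953, 45613, 59861 and 51694 peaks at days 1, 3, 5 and 7. Of the day 1 peaks 47% (exact 95% interval 46.6 to 47.4%) had no peak over them at day 7 and are called closed sites (28657), and of the day 7 peaks 36.3% (35.9 to 36.7%) had none at day 1 and are called opened sites (18754). The Cdh1 locus (chromosome 8, 106603350 to 106670247) held 3, 3, 6 and 7 peaks over these days. At day 7 the closed sites overlapped a peak for 34.1% (33.5 to 34.6%) in shYthdf2 and 18.5% (18 to 18.9%) in shYthdf3, and the opened sites for 74.9% (74.2 to 75.5%) in shYthdf2 and 47.6% (46.9 to 48.3%) in shYthdf3. At day 5 the opened sites were open for 57.6% in shLuc, 44.5% in shYthdf2 and 29.2% in shYthdf3. The lists differed in length, with 55577 peaks in shYthdf2 and 43725 in shYthdf3 at day 5, and 75558 and 52389 at day 7. With the same number of the widest peaks in each list (43725), which also redefined the sites (18843 closed and 18288 opened), the closed sites at day 7 were 21.4% in shYthdf2 and 18.9% in shYthdf3 and the opened sites 52.8% and 50.3%, and at day 5 the opened sites were 49% in shLuc, 43.5% in shYthdf2 and 40.8% in shYthdf3. With the sites as first defined and the shYthdf2 list of day 7 shortened to its 52389 widest peaks, the shYthdf2 shares were 20.6% (20.2 to 21.1%) of closed and 53.1% (52.4 to 53.8%) of opened sites. The intervals cover counting error only.

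**Figure D4:**
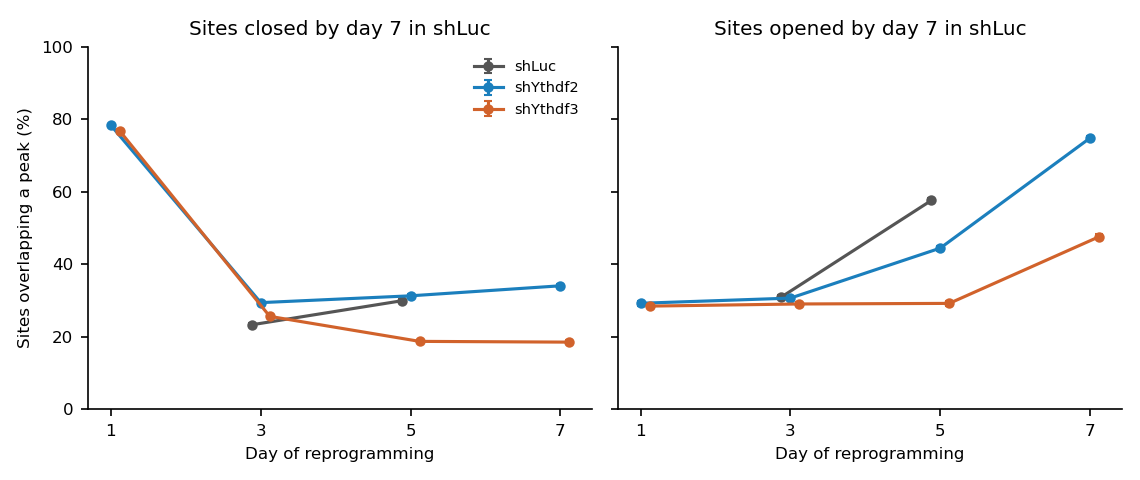
Percent of the 28657 closed sites (left) and the 18754 opened sites (right) that overlapped a peak on each day, with 1 library per point and bars of the exact 95% binomial interval. The sites were defined on the shLuc lists of days 1 and 7, which are not drawn, and at day 7 the opened sites stood at 74.9% in shYthdf2 and 47.6% in shYthdf3.

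TEAD2 binding at day 1 was compared with accessibility and expression. The 7805 TEAD2 peaks had a median width of 218 bases. Of them 86% (exact 95% interval 85.2 to 86.7%) overlapped a shLuc day 1 accessible site, and 72.8% (71.8 to 73.8%) a day 7 site, with 81.4% for shYthdf2 and 72.4% for shYthdf3 at day 7. With equal numbers of the widest peaks the day 7 values were 70.6% in shLuc, 73.1% in shYthdf2 and 69.7% in shYthdf3. Of shLuc sites kept from day 1 to day 7, 17.1% overlapped a TEAD2 peak, against 4.03% of closed and 1.05% of opened sites. Opened sites by definition lacked a shLuc day 1 peak, which 86% of TEAD2 peaks overlapped, so their low share was largely fixed in advance. Of 35088 placed genes 16.5% had a peak within 5 kb. Among placed genes measured in the time course the share was higher, with 5071 that had such a peak and 12840 that had none. Of the fixed lists 12 of 19 m6A genes did, 11 of 17 Hippo components, 14 of 28 cell cycle genes, 13 of 16 immediate early genes, 8 of 20 YAP-TEAD targets and 1 of 30 pluripotency genes, and no difference between these shares was tested. The other lists are not given here. Bound m6A genes included Ythdf2 (chromosome 4, 132212168 to 132212376) and Ythdf3 (chromosome 3, 16183120 to 16183462). Of 5788 genes with a peak within 5 kb, 5071 were measured in the time course. In shYthdf2, 146 of them were higher (2.88%, against 2.2% of other genes) and 91 lower, and in shYthdf3 158 were higher and 168 lower. As a set they did not pass limma camera in shYthdf2 (adjusted p = 0.991), shYthdf3 (0.792) or shTead2 (median log2 change -0.07, adjusted p = 0.598).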

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

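Tests of leaving out 1 library for endothelial markers, of the number of peaks called and of other splits of the libraries were chosen only after the result was seen. The tests of scaling, of 1 library and of low-oxygen genes for glycolysis, and of further endothelial genes, were set before their results were seen.

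Glycolysis genes were higher with both hairpins in ES and iPS cells, by medians of 0.66, 0.68, 0.48 and 0.53, and the effect in MEFs minus that in ES cells had a median of -0.70 in shYthdf2 and -0.79 in shYthdf3. Median-ratio scaling left the lowest of the 4 medians at 0.48, and leaving out 1 library left it at 0.38 (without iPS shYthdf2 replicate 2), so neither the TPM scaling nor a single library accounts for the rise. A broader response to low oxygen is a candidate explanation: 19 hypoxia targets outside glycolysis, which left out Ndufa4l2, Bnip3 and Egln3 since their values had been seen, had medians of 0.50, 0.31, 0.43 and 0.47 (limma camera with an estimated correlation, adjusted over the 6 cell line comparisons, adjusted p = 0.00372, 0.00766, 0.00518 and 0.00372), with 7, 4, 5 and 6 members called higher. In MEFs the medians of those targets were 0.13 and -0.13 (adjusted p = 0.614 and adjusted p = 0.978). Ddit4 and Bhlhe40 in that list also stand in other fixed lists, and whether such a response came from the readers' loss or from the density or oxygen of the cultures stays open, since each arm was a separate culture.

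Endothelial markers were higher in the libraries with shTead2, with a median of 3.04, and both libraries showed it, at 3.29 and 2.80 against the shLuc mean, with 8 of 9 members higher in both, so 1 library does not set it. Endothelial cells mixed into those cultures may account for it: 13 further endothelial genes, written down before they were looked at, had a median of 1.39 (1.98 and 0.82 in the libraries), and 9 of 13 were higher in both. Flt4 was at 169 ± 188 against 10.8 ± 2.01 TPM and Eng at 46.8 ± 33.7 against 14.8 ± 1.19 TPM. Cd34 (147 against 139 TPM) and Tek (15.2 against 13.7 TPM) were only slightly higher, and S1pr1 (53.9 against 62.6 TPM) was lower. Sox17 is also in the primitive endoderm list. In shTead2 replicate 1 the reprogramming factors stood apart, with Pou5f1 at 693 TPM (1398 in replicate 2, 1380 and 1415 in shLuc), Sox2 at 508 TPM (1037, and 1059 and 1046) and Klf4 at 534 TPM (1104, and 1122 and 1237), while the endothelial markers were higher in both libraries. Whether replicate 1 held more cells that were not infected stays open, an effect of Tead2 on these genes cannot be excluded, and no sort or gate is given in the sources used here.

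More of the sites that closed in shLuc had a peak at day 7 with shYthdf2 than with shYthdf3, 34.1% against 18.5%, a gap of 15.6 percentage points. The lists held 75558 and 52389 peaks, and with equal numbers of the widest peaks in every list, which also redefined the closed sites, the gap was 2.51 points. With the closed sites kept and the shYthdf2 list alone shortened to its 52389 widest peaks it was 2.14 points, so the number of peaks called may account for most of it. Both settings left out the narrowest peaks, and width is not strength. With 1 library per arm, a difference in accessibility and a difference in depth or quality stay open.

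The other differences between groups are given as values, and with shYthdf2 its target fell less in MEFs than in ES or iPS cells. The effect of shYthdf2 differed between day 7 and day 1 for 1 gene, between MEFs and ES cells for 210, between iPS and ES cells for 3 and between MEFs and iPS cells for 131. The effect of shYthdf3 differed for 132, 1 and 82 genes in the last 3 of these. From day 1 to day 7 the shYthdf3 effect moved by -0.60 in the median of glycolysis genes and by -0.55 in that of ribosomal protein genes. The shYthdf2 effect on glycolysis genes moved by -0.50 (adjusted p = 2.22e-05, and adjusted p = 0.0651 with an estimated correlation). Between MEFs and ES cells the shYthdf2 effect on cell cycle genes differed by -0.35 in the median. For shYthdf2 that same difference was -3.09 for Ndufa4l2, -2.40 for Bnip3, -2.14 for Slc16a3, 1.90 for Halr1, 1.84 for Gbx2, 2.07 for Clec3b, 1.94 for Agt, 1.75 for Clu, -1.66 for Prl2c2 and -1.53 for Hmga2. For shYthdf3 it was -3.22 for Ndufa4l2, -3.41 for Slco1a6, -2.44 for Bnip3, -1.77 for Pgm2, -2.74 for Col26a1, 1.39 for Spry4, 0.95 for Nfu1, 0.88 for Selenoh, 0.83 for Pcolce and -1.21 for Lin54. Snora70 and Snord15a gave fitted differences of 6.35 and 5.25 in both knockdowns, which are no bounds, since both were listed at 0 in every ES knockdown library and in every MEF library.

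Other splits of the libraries into groups of the same sizes within each day asked whether chance could give the counts. For shYthdf2 over the 4 days 2 of 100 splits gave as many genes as the real 755. The other one, which follows replicate number, gave 2395 genes, 3.17 times the real count. That points to a structure of the samples along replicate number, and with it as a block the real count was 1609. For shYthdf3 over the 4 days 1 of 100 splits, the real one with 1121 genes, reached that count (highest other 302), and the split by replicate number, run apart from these, gave 2161 (2228 with the block). For shYthdf2 against shYthdf3 1 of 100 reached 1493 (highest other 1074), and the split by replicate number gave 1779 (2746 with the block). Of the 100 splits, 22, 18 and 23 in these 3 comparisons part as many pairs as the real one, which is counted among them, and their highest other was 1, 24 and 0 genes. The 18 for shYthdf3 are too few for a share under 0.05. The others keep some libraries of the same number and day together in an arm. For persistence chance cannot be excluded: 33 of 100 splits reached the 3 genes of shYthdf2 (highest other 535) and 41 of 100 the 1 gene of shYthdf3 (highest other 162). For DMSO the 18 possible splits are too few for a share under 0.05, with the real 66 and highest other 42 in shYthdf2, where that other is the split by replicate number, and 135 and 9 in shYthdf3, where 1 of the 18, the real one, reached the count.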

How the results depend on the processing

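Leaving out day 1 or 7, simulated spread with the block, and the shortened shYthdf2 peak list were chosen only after the result was seen. The others were planned, except the widest peaks, which replaced the strongest. TPM holds no depth, so what depth limits in expression is unknown, and with 2 libraries per group the counts of called genes rested on single libraries in most comparisons. Of 117 called named-gene results 0 changed sign in any alternative run. Choosing genes without overlap or with 1 sign at each day or hour largely fixed that. Of 41 not called 14 did. With 1 library left out, Ythdf1 in shLuc from day 1 to day 7 was at -0.46 to 0.41 and Ythdf3 there at -0.74 to 0.19. Tead2 in shYthdf2 ES cells was then at -0.13 to 0.28. Of 158 named-gene results 151 stayed on their side of the threshold with median-ratio scaling, 140 without the filter, 142 with a pseudocount of 0.1 and 148 with the block, and the others became weaker except for 2 that became stronger with the block, both for Tead2. With 1 library left out 1058 of 1232 such values stayed on their side, 171 became weaker and 3 stronger. Where a value moved, the cause was not tested. Of 24 counts with at least 10 genes, 11 had a share of higher calls that crossed 50% in an alternative. With median-ratio scaling it went from 41.9 to 52.8% for shYthdf3 at day 3, from 52.6 to 44.7% for shYthdf2 at day 5, from 41.3 to 53.4% for shYthdf3 in iPS cells and from 50.8 to 47.9% between the knockdowns. The block moved that last share to 48% and that of shYthdf2 at day 3 from 47.1 to 56.9%. Without the filter it went from 39.1 to 51.5% for shYthdf3 at day 1 and to 46.8% for shYthdf2 at day 5, and with a pseudocount of 0.1 from 52.3 to 49.5% for shYthdf2 in ES cells. With 1 library left out it was 89.6% for shYthdf3 at day 1 (without its replicate 2) and 69.1% at day 3 (without its replicate 1), and at day 7 it went from 60.7 to 33.3% for shYthdf2 (without shLuc replicate 1) and from 61.5 to 41.7% for shYthdf3 (without shLuc replicate 2). In ES cells it was 45.1, 48.4 and 49.3% for shYthdf2 without shLuc replicate 1, shYthdf2 replicate 1 or shYthdf2 replicate 2, and went from 57.3 to 47.4% for shYthdf3 without its replicate 2. Over the 4 days it went from 52.5 to 49.7, 48.7 and 45.9% for shYthdf3 without shLuc day 5 replicate 2, shLuc day 7 replicate 2 or shYthdf3 day 7 replicate 1. Between the knockdowns it was 49.7, 47.1 and 47.6% without shYthdf2 replicate 1 of day 1, 3 or 7, 46.7 and 45.8% without shYthdf3 day 1 replicate 1 or 2, and 43.5% without shYthdf3 day 7 replicate 2. With a pseudocount of 0.1 the counts were 12, 7 and 23 for shYthdf2 at days 1, 3 and 5, 35, 17 and 75 for shYthdf3 there, 0 for the shYthdf2 effect at day 7 against day 1, 310 for shYthdf3 in iPS cells, 190 in MEFs, and 5 and 2 for persistence in shYthdf2 and shYthdf3. Without the filter they were 17 and 34 for shYthdf2 at days 1 and 3, 18 and 26 for the effects of shYthdf2 and shYthdf3 at day 7 against day 1, 0 for shTead2, and 5 and 19 for persistence. With median-ratio scaling they were 11 for shYthdf2 at day 1, 3 for the shYthdf3 effect at day 7 against day 1, 51 for shYthdf3 in MEFs, 86 for its difference between MEFs and ES cells, 1 for shYthdf2 persistence and 73 for shYthdf3 in DMSO. With the replicate block shYthdf2 gave 26, 137, 182 and 73 genes by day and 1609 over the days, shYthdf3 gave 141, 195, 422 and 343 by day and 2228 over the days, the knockdowns differed in 2746 genes, and the shYthdf3 effect differed between day 7 and day 1 in 34. The block also gave 2350 for shLuc day 7 against day 1, 72 for shYthdf3 in MEFs, 44 for its difference between MEFs and ES cells, 4339 for actinomycin D at 4 h, 10 and 10 for persistence, and 330 and 737 in DMSO. In the cell lines and the Tead2 experiment, where the numbers pair no samples, it ended the calls of Ythdf3 (adjusted p = 0.0706), Pcca, Nfu1 and Sox5 in shYthdf3 MEFs, Slco1a6 and Pitx3 in shYthdf3 ES cells, Snora41 in shYthdf2 ES cells, Otx2 in shYthdf2 iPS cells, Mettl3, Pabpc1, Dcn, Lum, Ccng1 and Cdkn1a in shYthdf2 MEFs, and S100a8 in shTead2, and of no other gene named against a control. One fit of all 46 libraries gave 168 genes for shTead2. The shYthdf2 mean without day 7 gave 395 genes. The covariance of the knockdowns' effects in simulated unchanged groups was 0.042 in place of 0.0706 with the spread left by the block. With an estimated correlation 22 list tests passed in place of 168. With 500 genes the MEF-high set was higher in shYthdf2 by 0.10 (adjusted p = 0.00514, range over the sizes 0.00514 to 0.532, and adjusted p = 0.663 with an estimated correlation). With 50 genes the mean of the ES-high set was -0.03 in shYthdf2 in place of 0.05, and -0.08 in shYthdf3 in place of 0.12, and neither passed at any size. With an overlap of at least 50% the closed sites stood at 32% in shYthdf2 and 16.5% in shYthdf3, the opened sites at 72.4% and 43.8%, the share of shLuc day 1 peaks closed at 53.5%, that of day 7 peaks opened at 39.5%, and TEAD2 peaks in shLuc sites at 80.9% at day 1 and 66.2% at day 7. TEAD2 peaks then lay in 8.43% of kept, 3.25% of closed and 0.945% of opened sites. With equal numbers of the widest peaks the same values were 21.4% for shYthdf2 closed sites, 52.8% and 50.3% for opened sites, 43.1%, 41.8%, 80.2% and 70.6%, and 21% of kept, 5.26% of closed and 1.66% of opened sites held a TEAD2 peak. That setting also redefined the sites, and with the sites kept and the shYthdf2 day 7 list shortened to its 52389 widest peaks the shYthdf2 values were 20.6% of closed and 53.1% of opened sites. For the shLuc change from day 1 to day 7, the MEF-high set had adjusted p = 0.135 with an estimated correlation and 500 genes. Leaving out 1 library gave 2 to 6, 0 to 71, 0 to 21 and 1 to 15 genes for shYthdf2 at days 1, 3, 5 and 7, and 3 to 473, 0 to 55, 4 to 42 and 12 to 53 for shYthdf3. It gave 380 to 775 for shYthdf2 over the days, 770 to 1147 for shYthdf3, 1018 to 1511 between them, 0 to 5 and 0 to 306 for the effects at day 7 against day 1, and 699 to 901 for shLuc. It gave 207 to 366 and 131 to 224 in ES cells, 104 to 174 and 123 to 155 in iPS cells, 34 to 177 and 17 to 548 in MEFs, 54 to 115 and 32 to 574 for MEFs against ES cells, 3 to 300 for shTead2, 1315 to 1990 and 4093 to 4828 for actinomycin D at 4 h and 8 h, 0 to 9 and 1 to 5 for persistence, and 36 to 72 and 66 to 105 in DMSO.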

Other observations

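Some gene groups were not described above. Over the 4 days in shYthdf2 the median log2 change was -0.03 for the 13 CCR4-NOT genes and 0.02 for the 13 PAN2-PAN3 genes (limma camera adjusted p = 0.794 for both), 0.15 for pluripotency genes (0.216), -0.22 for the 4 reprogramming factors (0.603), 0.17 for Hippo components (0.193) and 0.10 for inflammatory genes (0.314). It was -0.14 for glycolysis (0.41), -0.10 for oxidative phosphorylation (0.286), -0.10 for ribosomal proteins (0.327) and 0.26 for mitochondrial transcripts (0.283), and the last passed with the block (0.0229). In shYthdf3 the CCR4-NOT and PAN2-PAN3 genes had medians of -0.03 and -0.01 (0.877 and 0.703). Of markers for other cell types in shYthdf2, those of macrophages (0.31, adjusted p = 0.216), skeletal muscle (0.07, 0.836), neural cells (-0.07, with the test pointing up, 0.914), keratinocytes (0.33, 0.532), trophoblast (-0.01, 0.794), primitive endoderm (0.36, 0.154), endothelium (0.03, with a mean of -0.05, 0.836) and epiblast (0.09, 0.794) did not pass. The ES-high and MEF-high sets did not pass over the 4 days in shYthdf2 (0.05 and 0.06, adjusted p = 0.411 and 0.109) or shYthdf3 (0.12 and -0.04, 0.406 and 0.322). On single days ES-high genes were higher in shYthdf2 at day 7 by a mean of 0.26 (adjusted p = 0.00342, and adjusted p = 0.196 with an estimated correlation) and in shYthdf3 at day 1 by 0.16 (adjusted p = 0.02, and adjusted p = 0.28 with an estimated correlation). MEF-high genes had a mean of -0.34 in shYthdf3 at day 1 (adjusted p = 0.00342, and adjusted p = 0.585 with an estimated correlation). From day 1 to day 7 the shYthdf3 effect on MEF-high genes differed by 0.51 (adjusted p = 0.00342, and adjusted p = 0.585 with an estimated correlation), and the shYthdf2 effect on ES-high genes by 0.26 (adjusted p = 0.0234, and adjusted p = 0.28 with an estimated correlation). MEF-high genes were higher in shYthdf2 than in shYthdf3 over the 4 days by 0.10 (adjusted p = 0.0144, and adjusted p = 0.717 with an estimated correlation). ES-high genes were higher with shTead2 by 0.43 (adjusted p = 0.00035, and adjusted p = 0.2 with an estimated correlation).

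From day 1 to day 7 in shLuc, macrophage markers had a median of -0.57 over 13 genes (adjusted p = 0.00604, and adjusted p = 0.276 with an estimated correlation), Hippo components -0.42 over 17 (0.0162, and adjusted p = 0.39 with an estimated correlation), primitive endoderm genes -0.85 over 6 (0.0456, and adjusted p = 0.272 with an estimated correlation) and reprogramming factors -0.71 (0.0456, and adjusted p = 0.276 with an estimated correlation), with Pou5f1 at 3163 ± 681 TPM at day 1 and 1496 ± 252 TPM at day 7.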
